A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

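The deposited table of counts was taken as given: per the submitters' processing notes, reads were aligned to the sacCer3 genome with STAR and handled with SAMtools, and DESeq2 was used by the authors, all without versions. Those steps were not repeated here, and no value computed by the authors was used. Cells grew at 30 °C to an OD600 of 0.6 to 0.8 and received 1 µg/ml SM for 25 min, and 2.4 µl of a 1:100 dilution of the ERCC mix went into 1.2 µg of total RNA, per the sample labels. Libraries were stranded, rRNA-depleted and paired-end. Which strand was counted, and whether a read shared between copies was counted, are not given in the sources used here, so near-identical copies, overlapping genes and antisense reads stay uncertain.

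The table holds 6692 yeast features and 92 spike-in species, of which 74 were seen in every library. Of the yeast identifiers 6008 match the RefSeq annotation of the R64 assembly, 6000 of them at the same coordinates, and the 684 without a match hold 0.72% of yeast counts. All feature lengths are multiples of 3, as for coding length. All spike-in values are even while 50.5% of yeast values are, so spike-in fragments seem to be counted per read and yeast fragments per pair; a factor common to all libraries does not touch the scaling. Spike-in counts ran from 454216 to 651122 per library. Yeast counts in M per library were 40.0, 34.9 and 39.7 (WT without SM), 35.8, 37.5 and 31.1 (WT with SM), 41.7, 42.3 and 42.3 (spt3), 45.7, 37.9 and 36.8 (spt8) and 24.8, 29.5 and 35.7 (gcn5). The ratio of yeast counts in M to the spike-in factor was 31.9 ± 0.93, 37.6 ± 3.62, 40.3 ± 7.56, 39.9 ± 2.91 and 34.2 ± 7.58 (mean ± SD, n = 3) in the same order. All 15 libraries were kept.

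Size factors are medians of ratios over the spike-ins. Unless another fit is named, tests used edgeR 4.0.16 quasi-likelihood with all 5 groups, genes kept by filterByExpr, and Benjamini-Hochberg (BH) adjustment with calls at 0.05. R was 4.3.3, limma 3.58.1 and DESeq2 1.42.0; Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served the tables and figures. The common coefficient of variation between replicates is 16.1% with spike-in scaling and 7.9% with TMM. The ± values are SD of scaled counts, and SE is that of the edgeR log2 fold change. Contrasts, alternatives, gene lists and the spike-in scaling were chosen before the data were examined, from the labels. Genes are named in the text by a rule written beforehand. It takes the 3 targets and GCN4; the 8 largest rises and 8 largest falls per comparison (5 and 5 between deletion strains) among called genes with a symbol, a cpm of 10 or more and no overlap between groups; and up to 4 members of each list, those called with the largest change or, with none called, the most abundant. Genes deleted in the parent strain, LEU2, MET15 and URA3 among them, and the target itself are left out of the largest changes, and further list members appear in counts.

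Lists were tested with limma camera at a preset correlation of 0.01, BH over 31 lists per comparison. Of 33 lists fixed beforehand, those for small nucleolar RNAs and for Ty elements matched 0 features and give no result; Ty features were found by another pattern. Calls upward and downward were 6 and 11 for SM in WT, 1 and 4 for spt3, 1 and 6 for spt8, 2 and 5 for gcn5, 4 and 4 for spt3 against spt8, 2 and 4 for spt3 against gcn5, and 3 and 6 for spt8 against gcn5. With an estimated correlation none of them holds by spike-in scaling. With TMM 9 hold: arginine, histidine, lysine, sulfur, reporter panel, chaperone, inositol and other-cell-type lists for SM, and the a-specific list for gcn5. By spike-ins a shift of a whole library (SD 0.187 log2 within groups) moves all its genes together. It raises the correlation estimated for any list, so losing a call there does not by itself speak against that list.

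In the self-test, real dispersions were kept, 200 genes were given a known change and the libraries a scaling spread of 0.187 log2 within groups. Each comparison was simulated a single time, so its shares hold the scaling errors of that draw. By spike-ins the median unchanged gene was shifted by −0.171 log2 in spt3 and 0.193 in spt3 against gcn5. By spike-ins a 1.5-fold change was found for 77.6% of genes (SM in WT), 43.3% (spt3), 47% (spt8), 74.6% (gcn5), 16.4% (spt3 against spt8), 62.7% (spt3 against gcn5) and 86.6% (spt8 against gcn5). At 2-fold these are 97%, 100%, 100%, 100%, 94%, 100% and 100%, and at 4-fold 97% for SM and 100% for each other comparison. With TMM the shares at 1.5-fold are 92.5%, 97%, 90.9%, 92.5%, 89.6%, 89.6% and 88.1%. False calls among unchanged genes were 0.05%, 0.19%, 0.05%, 0.14%, 0.03%, 1.2% and 0.06% by spike-ins, and at most 0.38% with TMM. A planted list was found in every comparison, and at most 2 of 30 other lists were called by spike-ins. Shared controls were simulated from the same dispersions with groups that do not differ.

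Replicates of a group are more different than counting noise alone: the mean squared difference per gene is 10.1 to 101 times that of counting, so none was deposited as a copy of another. The spread between spike-in species was 0.33, 0.222 and 0.239 log2 in the gcn5 libraries and 0.064 to 0.143 in all others.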

Results

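Budding yeast of one laboratory strain (BY4741, mating type a) grew in medium without isoleucine and valine, with or without sulfometuron methyl (SM), which blocks synthesis of those amino acids and so activates the transcription factor Gcn4. The libraries cover 5 groups of 3: wild type (WT) without SM, WT with SM, and strains lacking SPT3, SPT8 or GCN5, all with SM for 25 min. No deletion strain without SM is included, so a strain's response to SM cannot be told from its level before SM. Spt3 and Spt8 are subunits of the SAGA coactivator linked to the TATA-binding protein, and Gcn5 is its histone acetyltransferase. The deposited table gives read counts for 6692 yeast features and 92 synthetic spike-in RNAs (ERCC) added per amount of total RNA. Depth ran from 24.8 to 45.7 M yeast fragments per library. Spike-ins made up 1.18% to 1.80% of all deposited counts, a share that is lower in fragments, as they seem to be counted per read and yeast genes per pair. The spike-ins set the scale here, so a gene that rises did so per amount of total RNA. Another scaling, TMM, takes most genes as unchanged. Totals are printed under both, and list calls that differ between them stand beside the result or in the closing section. The p-values measure only the spread between these samples, which may be technical: n = 3 per group, and what separates the 3 (colony, culture or day) is not given in the sources used here.

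The deleted gene was nearly silent in each strain and nowhere else. SPT3 (YDR392W, chromosome IV, 1258696 to 1259709) had 1, 3 and 3 raw counts in the spt3 libraries, and its scaled mean was 2.1 ± 0.8 (SD) against 983.6 ± 180.1 in WT with SM. The raw counts of SPT8 (YLR055C, chromosome XII, 251272 to 253080) were 16, 17 and 11 in the spt8 libraries, with a scaled mean of 14.8 ± 3.7 against 1228.5 ± 156.6. For GCN5 (YGR252W, chromosome VII, 996869 to 998188) they were 12, 29 and 18 in the gcn5 libraries, 21.9 ± 7.2 against 4199.1 ± 536.0 after scaling. In log2 the differences for SPT8 and GCN5 are −6.38 and −7.56, and for SPT3, with so few counts, no fold is given. Of the genes missing from the parent strain, LEU2 and MET15 had 0 to 6 counts in 14 libraries, but 70 and 82 in library 1 of WT without SM. By spike-ins no strain changed the mRNA of the other targeted genes; with TMM SPT8 was higher by 0.33 in spt3, and SPT3 by 0.33 in gcn5. GCN4 itself (YEL009C, chromosome V, 138918 to 139763) had 20124 to 40574 raw counts in every library. Its differences from WT with SM were 0.27, 0.29 and 0.37 log2 in the spt3, spt8 and gcn5 strains and passed the test in none of the strains by spike-ins. All 3 were called higher with TMM, with edgeR BH-adjusted p of 0.0182, 0.0265 and 2.53e-07.

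Of the 31 lists tested, arginine genes had the highest median rise with SM. All 10 genes of the arginine list rose in WT, by a median of 3.01 log2, or 2.47 above the median of all genes. ARG3, ornithine carbamoyltransferase (YJL088W, chromosome X, 268799 to 269815), rose from 507 ± 72 to 21807 ± 1324 scaled counts (5.43 log2, SE 0.21, edgeR BH-adjusted p = 1.83e-22). ARG1, argininosuccinate synthetase (YOL058W, chromosome XV, 219211 to 220473), rose from 3375.0 ± 307.1 to 59020.7 ± 2748.8 (4.13 log2, SE 0.18, edgeR BH-adjusted p = 2.29e-21). ARG56 rose by 3.67. In a panel of 16 genes commonly used as reporters of Gcn4 all 16 rose, with a median of 2.81, among them the vitamin B6 genes SNZ1 (4.28) and SNO1 (4.13). Every member also rose among the 6 histidine genes (median 1.80; HIS4 2.93, HIS5 2.69) and the 9 lysine genes (median 1.92; LYS20 2.58, LYS1 2.19). Of 13 aromatic genes 12 rose (TRP3 2.00, TRP4 1.89; with TMM 9 rose and 1 fell); by limma camera this list passes with TMM (BH-adjusted p = 0.00385, or 0.256 with an estimated correlation) and not by spike-ins (0.0816). In the sulfur list 18 of 23 rose and 3 fell (STR3 5.81, SUL1 3.02, but SAM2 −1.95). The branched-chain list gave 6 rises and 1 fall in 9 genes: LEU4 rose by 1.41 and ILV2 by 1.06, while LEU1 fell by 1.14 (with TMM 3 rises and 2 falls). Its median of 0.46 lies 0.07 below that of all genes, and the list did not pass (limma camera, BH-adjusted p = 0.857). Adjusted over each list alone, the counts were the same for arginine, histidine, lysine, sulfur, branched-chain and reporter genes. The camera test of limma gave BH-adjusted p of 5.77e-19 for arginine, 2.77e-19 for the reporter panel, 0.000991 for histidine, 0.000543 for lysine and 0.000991 for sulfur genes. With an estimated correlation these adjusted p become 0.325, 0.375, 0.685, 0.685 and 0.837 by spike-ins, and 0.0013, 0.00458, 0.0348, 0.0376 and 0.0348 with TMM.

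Chaperone and glycolysis genes fell. Of 18 chaperone genes 15 fell and 1 rose, the same adjusted over the list alone, with a median of −1.08. The cytosolic Hsp70 gene SSA2 (YLL024C, chromosome XII, 95566 to 97485) went from 44338.9 ± 1329.5 to 9749.0 ± 851.1 scaled counts (−2.19 log2, SE 0.19, edgeR BH-adjusted p = 7.35e-13). SSA1 fell by 2.10, the Hsp90 gene HSP82 by 1.84 and its cochaperone STI1 by 1.77. SSA1 and SSA2 are similar in sequence, so reads may be shared between them. In the glycolysis list 14 of 16 fell (15 over the list alone; median −0.62): TDH2 by 1.89, ADH1 by 1.31 and PDC1 by 0.92. INO1 fell by 1.34, as 5 of the 7 inositol genes did, and the hexose transporter gene HXT2 fell by 1.75. The limma camera test with BH adjustment gave 5.83e-15 for chaperones, 3.99e-10 for glycolysis and 0.000443 for inositol genes. Those adjusted p are 0.559, 0.591 and 0.685 with an estimated correlation; with TMM the first and the third hold, at 0.0138 and 0.0348. Also lower than other genes by limma camera were stress genes regulated by Msn2 and Msn4 (1 rise and 6 falls in 20; HXK1 −1.34), citrate cycle genes (1 and 5 in 13; MDH1 −1.67), respiratory genes (2 and 6 in 23), hexose transporters (1 and 3 in 7) and ergosterol genes (2 and 5 in 18). Over each list alone these counts are 0 and 5, 1 and 3, 2 and 6, 1 and 3, and 2 and 3. With TMM they are 0 and 17, 0 and 12, 1 and 20, 0 and 5, and 1 and 15. Their BH-adjusted p in limma camera were 2.71e-05, 0.000382, 2.8e-05, 0.00119 and 0.00276, and none holds with an estimated correlation (0.685 or above).

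Genes of other cell types and of mating also rose in SM. All 12 genes of a list specific to alpha cells or meiosis rose, also over the list alone (median 1.51, 0.97 above all genes), among them MF(ALPHA)2 by 3.44, SPO13 by 2.61 and the a-factor receptor gene STE3 by 2.55, from 528.3 ± 54.6 to 3096.0 ± 261.9 scaled counts. This list passed with limma camera (BH-adjusted p = 0.000991; 0.685 with an estimated correlation, and 0.0348 with TMM). Pheromone-pathway genes shared by both haploid mating types rose in 11 of 12 cases (PRM1 2.73, FUS1 1.75; with TMM 6 rose and 1 fell), and all 7 a-specific genes did (ASG7 1.62; 4 with TMM), though neither list stood apart from other genes by limma camera (BH-adjusted p of 0.2 and 0.357). The largest single rises were LDS1 (5.96, SE 0.27), a spore-wall gene, STR3, ARG3, the amino acid catabolism gene ARO10 (5.18, SE 0.22) and SRL4 (5.08).

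Over all 6564 genes tested, 3653 rose and 497 fell, and 2414 did not pass. At 2-fold or more, 1940 rose and 80 fell. Without WT library 3 with SM the number that fell is 321. The median gene rose by 0.54 log2 against the spike-ins, so rises are 88% of the calls; with TMM 2708 rose and 2445 fell, and rises are 52.6%. All 2708 of those and 497 of the falls carry the same call under both scalings, and 0 genes are called in opposite directions. Ribosomal protein genes show what the choice does: 32 of 132 rose (21 over the list alone; median 0.24) while limma camera places them below other genes (BH-adjusted p = 0.00616; 0.899 with an estimated correlation); with TMM 7 rose and 88 fell. Ribosome biogenesis genes likewise have 12 rises and 3 falls in 46 (11 and 3 over the list alone), a median of 0.11, and a limma camera call downward (BH-adjusted p = 0.00152; 0.899 with an estimated correlation), and with TMM 2 rises and 31 falls. GCN4 mRNA rose by 0.60 log2 (SE 0.16, edgeR BH-adjusted p = 0.00153), from 18972.4 ± 392.3 to 28823.8 ± 2793.4; with TMM the rise is not called (edgeR BH-adjusted p = 0.105). GCN5 mRNA rose by 1.04. SPT8 and SPT3 mRNA were not called by spike-ins (0.23 and 0.31), while TMM puts SPT8 down by 0.28 (edgeR BH-adjusted p = 0.00637). In 4989 genes (76%) the 3 libraries with SM and the 3 without did not overlap, where chance gives 10% if no shift is common to all genes. With TMM, which removes such a shift, and in a count added after the data were seen, these are 5356 genes (81.6%).

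**Figure D1:**
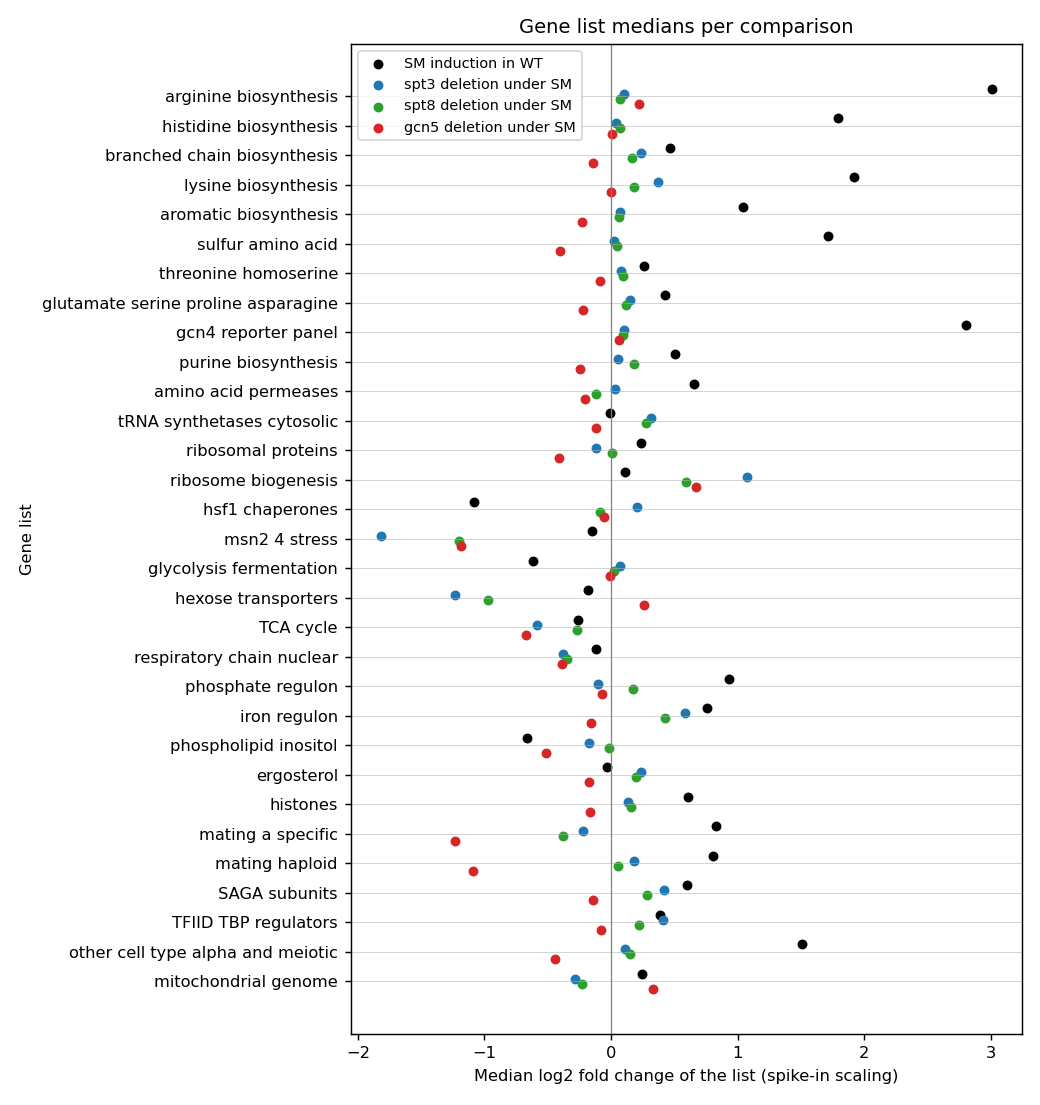
Median log2 fold change of the genes in each of 31 lists, scaled by spike-ins, for SM in WT (black) and for the spt3 (blue), spt8 (green) and gcn5 (red) strains against WT, all with SM. Arginine genes lie at 3.01 for SM and near 0 in the strains; stress genes regulated by Msn2 and Msn4 lie at −1.82, −1.20 and −1.18 in the 3 strains.

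In the spt3 strain 2 of 10 arginine genes fell relative to WT in SM. They were ARG3, which fell by 0.99 log2 (SE 0.17; 11000 ± 1438 against 21807 ± 1324 scaled counts, edgeR BH-adjusted p = 1.89e-05) and ARG56, which fell by 0.96 (edgeR BH-adjusted p = 1.5e-05); 8 did not pass. The counts are the same over the list alone, and the median is 0.10. Of the 16 Gcn4 reporter genes 2 rose and 3 fell (also over the list alone), with PCL5 at −0.55; with TMM, arginine genes gave 2 rises and 4 falls and reporter genes 6 and 4. Neither list passed with limma camera (BH-adjusted p of 0.509 and 0.904). Among single genes of the amino acid synthesis and permease lists, SER3 rose by 1.57, LEU1 by 1.22 and the sulfate permease gene SUL2 by 1.29. STR3 fell by 0.89, MET28 by 0.86 and the proline permease gene PUT4 by 1.11.

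Stress genes fell without Spt3. Of 20 genes regulated by Msn2 and Msn4, 18 fell (19 over the list alone), by a median of 1.82 log2. HXK1, a hexokinase (YFR053C, chromosome VI, 253592 to 255049), went from 15388.5 ± 1990.5 to 1052.5 ± 186.0 scaled counts (−3.87, SE 0.23, edgeR BH-adjusted p = 3.29e-16). GPH1, glycogen phosphorylase (YPR160W, chromosome XVI, 861306 to 864014), went from 31648.7 ± 5163.4 to 2680.2 ± 354.4 (−3.56, SE 0.22, edgeR BH-adjusted p = 1.14e-15). Also down were SOL4 (−3.51), DDR2 (−3.30) and GAC1 (−3.60), which targets a phosphatase to glycogen synthase. Hexose transporter genes fell in 6 of 7 cases (7 over the list alone): HXT7 by 2.78, HXT3 by 2.22 and HXT5 by 1.78. HXT6 and HXT7 are near-identical copies, so reads may be shared between them. SDH1 fell by 1.15, one of 9 falls in 13 genes of the citrate cycle (9 over the list alone), and the respiratory list gave 10 falls and 1 rise in 23 (11 and 1 over the list alone). By limma camera the BH-adjusted p were 2.86e-35 (stress), 1.66e-09 (hexose transport), 0.00153 (citrate cycle) and 0.00163 (respiration). Those adjusted p are 0.172, 0.279, 0.965 and 0.965 with an estimated correlation.

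Ribosome biogenesis genes rose without Spt3. Of 46 tested, 44 rose and 0 fell, also over the list alone, with a median of 1.08 log2 (limma camera, BH-adjusted p = 2.79e-18; 0.965 with an estimated correlation). DRS1, a helicase of the large subunit pathway, rose by 1.70 (SE 0.21), RRP12 by 1.64 and ENP2 by 1.57. Outside the list, MRD1, needed to process the rRNA precursor (YPR112C, chromosome XVI, 749256 to 751919), rose from 847.3 ± 150.5 to 3358.3 ± 746.1 scaled counts (1.99, SE 0.22, edgeR BH-adjusted p = 4.46e-09), and LTV1 rose by 1.98 (SE 0.22). The largest rise was that of HO, the mating-type endonuclease gene (2.22, SE 0.22). Of 132 ribosomal protein genes 2 rose and 0 fell (median −0.12), whereas with TMM 3 rose and 82 fell. In a list of TFIID and TBP regulator genes 6 of 15 rose (TAF7 1.35, TAF1 1.03; 11 rises and 2 falls with TMM), and so did 7 of 19 SAGA genes (SPT7 0.91, SPT20 0.82; 12 and 3 with TMM), with SPT3 the one that fell. Neither list passed by limma camera (BH-adjusted p of 0.097 and 0.74), though the first does with TMM (0.0345, or 0.883 with an estimated correlation). Ribosomal protein genes pass downward with TMM (limma camera, BH-adjusted p = 0.00701, or 0.924 with an estimated correlation) and not by spike-ins (0.193). Relative to genes with a mean count of 300 or more, their spike-in median is −0.263. Removing trends with gene length and GC content takes it to −0.073.

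Over all 6564 genes, 1426 rose, 919 fell and 4219 did not pass in the spt3 strain; 291 rose and 369 fell at least 2-fold. The median gene lies at 0.11 log2, and relative to it ribosome biogenesis genes are at 0.97 and stress genes at −1.92. With TMM 2223 rose and 2061 fell, and 0 genes are called in opposite directions under the 2 scalings. Without spt3 library 1 the number that rose is 781, and without WT library 3 with SM it is 865. Library 1 of spt3 has 48.85 M yeast fragments per unit of spike-in, above the group mean of 40.3 ± 7.56. In 3157 genes (48.1%, 10% by chance; 74.7% with TMM) the groups did not overlap. This comparison lies within one of the 2 sets into which the library names fall.

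Of the genes called without Spt8, 407 of 431 rises and 352 of 366 falls were also called in spt3. The totals are below those of spt3, but in spike-in fits of only the 2 groups they are close: 1742 rises and 766 falls in spt8, and 1574 and 960 in spt3. With TMM such fits call 3392 genes in spt8 and 4519 in spt3. Of the 20 stress genes 16 fell (17 over the list alone; median −1.20): HXK1 by 2.56 (SE 0.21; 2607.4 ± 785.9 scaled counts, edgeR BH-adjusted p = 2.21e-11), TKL2 by 2.56, DDR2 by 2.52 and GPH1 by 2.46. HXT7 fell by 2.64 (SE 0.20, edgeR BH-adjusted p = 1.1e-12) and HXT3 by 1.23, with 6 of 7 hexose transporter genes falling (7 over the list alone). GAC1 showed the largest fall (−2.81). Of 46 ribosome biogenesis genes 24 rose and 0 fell (34 and 0 over the list alone; median 0.60), such as RRP12 and DRS1, both by 0.94. Among permease genes 4 of 15 fell (PUT4 by 1.10, AGP1 by 0.94). The rises were led by ZPS1 (1.56, SE 0.36), FRM2 (1.42) and SER3 (1.35, SE 0.17, edgeR BH-adjusted p = 3.41e-07), though ZPS1 does not pass in DESeq2. By limma camera the BH-adjusted p were 1.28e-40 for stress, 6.31e-13 for hexose transport, 1.71e-10 for ribosome biogenesis and 0.00558 for permease genes. With an estimated correlation those adjusted p are 0.102, 0.124, 0.973 and 0.973. Citrate cycle (2 of 13 fell; SDH1 −0.79), respiratory (3 of 23; ATP3 −0.67) and a-specific genes (1 of 7, or 3 over the list alone; ASG7 −0.73) also passed downward, with limma camera BH-adjusted p of 0.00298, 1.52e-05 and 0.0132. Each is 0.973 with an estimated correlation. With TMM the falls are 12, 21 and 7 genes, and the ATP3 call ends without WT library 1 or 2 or spt8 library 1 or 2.

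In the arginine list 2 of 10 genes fell without Spt8 and 0 rose. ARG56 fell by 0.58 (edgeR BH-adjusted p = 0.0145) and ARG3 by 0.51 (SE 0.17; 15298 ± 1212 scaled counts, edgeR BH-adjusted p = 0.0425), and over the list alone 3 of 10 fell. Leaving out any one of the 6 libraries compared ends the ARG3 call, and any but WT library 3 ends the ARG56 call. Of the 16 reporter genes 1 fell, ARG3, and 0 over the list alone. STR3 fell by 1.13 and SUL2 rose by 0.99. The arginine list did not pass with limma camera (BH-adjusted p = 0.42).

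Counts for the spt8 strain are 431 genes that rose, 366 that fell and 5767 that did not pass; 40 rose and 158 fell at least 2-fold. They hang on single libraries. The number that rose is 223 without WT library 1, 122 without WT library 3, 185 without spt8 library 1, 118 without spt8 library 2 and 251 without spt8 library 3. The number that fell is 241 without WT library 2 and 226 without spt8 library 1. The median gene lies at 0.13 log2; relative to it stress genes are at −1.33 and ribosome biogenesis genes at 0.47. With TMM 1570 rose and 1382 fell, with 0 genes called in opposite directions under the 2 scalings. The groups did not overlap in 2935 genes (44.7%, 10% by chance; 61.1% with TMM). All spt8 and gcn5 libraries carry names of a second set that holds no WT library, so for these strains a difference between sets cannot be separated from the deletion.

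Mating genes fell in the gcn5 strain. Of 7 a-specific genes 6 fell, also over the list alone (median −1.23): ASG7, which acts in pheromone signalling (YJL170C, chromosome X, 101150 to 101779), from 3503.8 ± 509.1 to 342.0 ± 69.3 scaled counts (−3.36, SE 0.19, edgeR BH-adjusted p = 1.37e-16), BAR1 by 1.89 and the a-factor gene MFA1 by 1.83. Of 12 haploid mating genes 10 fell (10 over the list alone; median −1.09). FAR1, which arrests the cell cycle in mating (YJL157C, chromosome X, 123836 to 126328), went from 17348.1 ± 2237.4 to 2675.5 ± 1015.6 (−2.70, SE 0.21, edgeR BH-adjusted p = 1.03e-12), and FUS1 fell by 1.75. AFB1, another a-cell gene, fell by 3.07 and FMP46 by 3.09. The limma camera test with BH adjustment gave 3.69e-07 for a-specific and 4.49e-05 for haploid genes. With an estimated correlation both adjusted p are 0.972; with TMM the a-specific call holds at 0.0053. The list of alpha-cell and meiotic genes gave 2 rises and 5 falls in 12 (2 and 6 over the list alone; SPS4 −1.93).

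Ribosome biogenesis rose and stress genes fell in this strain as well. Of 46 biogenesis genes 34 rose and 0 fell (38 over the list alone; median 0.68), among them ENP2 by 1.41 and RPA34 by 1.36. Of 20 stress genes 18 fell and 1 rose (19 and 1 over the list alone; median −1.18), among them SOL4 by 2.14 and GPH1 by 1.87. The 3 gcn5 libraries each show both, with medians relative to all genes of 0.81 to 0.97 for biogenesis and −1.20 to −0.82 for stress genes. Ribosomal protein genes fell in 72 of 132 cases (81 over the list alone; median −0.41), with RPL43A at −2.21; many of these genes have a close copy, so their reads may be shared. Relative to genes with a mean count of 300 or more, their median is −0.241. Removing trends with gene length and GC content takes it to −0.119. The BH-adjusted p of limma camera were 1.4e-16, 2.05e-08 and 0.000414, each 0.972 with an estimated correlation. HXT2 rose by 1.32 while HXT7 fell by 1.21, leaving the hexose list without a common direction. In the sulfur list 11 of 23 fell and 0 rose (12 over the list alone), led by MET2 (−2.01), though with TMM 5 rose and 12 fell. Citrate cycle genes passed downward (10 of 13 fell, 12 over the list alone; SDH1 −1.09) and mitochondrially encoded genes upward (4 rose and 1 fell in 8), both with a limma camera BH-adjusted p of 0.0452, or 0.972 with an estimated correlation. Both calls end with the replicate number as a block (limma camera, BH-adjusted p of 0.0571 and 0.0545), and the mitochondrial call also ends with TMM (0.0949). Removing the same trends takes the relative median from −0.503 to −0.277 for citrate cycle genes, and from 0.506 to 0.234 for mitochondrial genes (6 members used).

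ARG3 rose a little in the gcn5 strain, by 0.60 log2 (SE 0.17; 33123 ± 5849 scaled counts, edgeR BH-adjusted p = 0.00441), as did ARG56 (0.61, edgeR BH-adjusted p = 0.00266) and CPA1 (0.67). In the arginine list 4 rose and 2 fell (ARG4 by 0.55, a call that ends without gcn5 library 1), also over the list alone, with a median of 0.22. Of the 16 reporter genes 2 rose and 1 fell, among the rises HIS5 (0.61). With TMM arginine genes gave 7 rises and 2 falls and reporter genes 10 and 1. By spike-ins neither list passed with limma camera (BH-adjusted p of 0.194 and 0.283). With TMM the arginine list passes upward (limma camera, BH-adjusted p = 0.0439, or 0.836 with an estimated correlation).

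In total 691 genes rose, 1994 fell and 3879 did not pass without Gcn5; 175 rose and 628 fell at least 2-fold. The median gene fell by 0.19 log2 against the spike-ins, and rises are 25.7% of the calls. This shift is less certain than in the other strains. Spike-in species differed by an SD of 0.33, 0.222 and 0.239 log2 in the gcn5 libraries, against 0.064 to 0.143 in all others. The ratio of yeast counts in M to the spike-in factor also overlaps, with 29.39 to 42.95 in gcn5 and 33.98 to 41.21 in WT with SM. With TMM 2241 rose and 2189 fell (50.6% rises), with 0 genes called in opposite directions under the 2 scalings. Relative to the median gene, a-specific genes are at −1.05, haploid genes at −0.90 and ribosome biogenesis genes at 0.86. Library 3 of gcn5 has 42.95 M yeast fragments per unit of spike-in, against 30.3 and 29.39 in the other libraries of the group. Without it 3364 genes fall, and without WT library 3 the number that rose is 426. The groups did not overlap in 2700 genes (41.1%, 10% by chance; 67.6% with TMM).

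**Figure D2:**
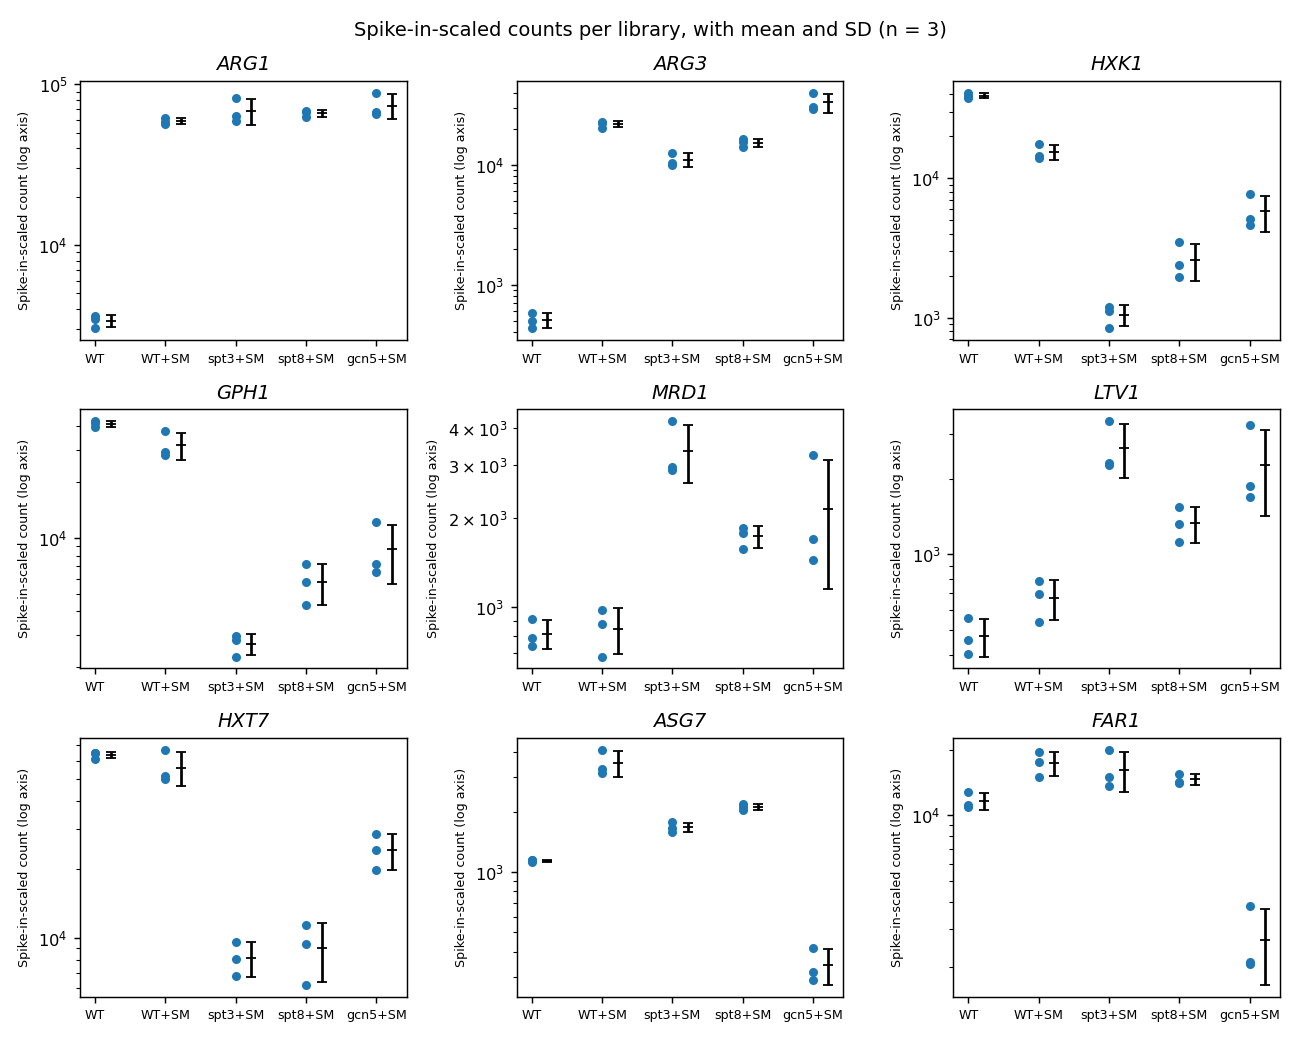
Scaled counts of 9 genes in each library (points) with the mean and SD of 3 libraries, on a log axis. ARG1 and ARG3 rise with SM in WT by 4.13 and 5.43 log2; HXK1 changes by −3.87 in spt3 and −2.56 in spt8, and ASG7 by −3.36 in gcn5.

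Over all lists of amino acid synthesis together, 69 and 78 of 89 genes did not pass by spike-ins without Spt3 or Spt8. Of all 6564 genes tested, 4219 and 5767 did not pass either. In these 8 lists, 70 genes rose in WT with SM, 6 fell and 13 did not pass (71 and 6 over the list alone; median 1.32, 0.78 above all genes). Compared with WT in SM, 14 rose and 6 fell in spt3 (median 0.12; 11 and 5 over the list alone), 7 rose and 4 fell in spt8 (0.09; 7 and 4), and 6 rose and 24 fell in gcn5 (−0.16; 6 and 23). Relative to the median gene those medians are 0.02, −0.04 and 0.02. With TMM rises and falls are 32 and 29 in spt3, 18 and 19 in spt8, and 33 and 27 in gcn5, where the median turns to 0.04. Of the 58 genes that SM raised under both scalings, such as ARG1 and HIS4, 8 rose and 5 fell in spt3 (7 and 4 over the list alone). In spt8 4 rose and 4 fell (4 and 4), and in gcn5 6 rose and 14 fell (6 and 13). With TMM rises and falls among them are 23 and 18 in spt3, 10 and 13 in spt8, and 24 and 17 in gcn5. None of these 8 lists passed by limma camera with spike-ins in any of the strains, though arginine passes upward in gcn5 with TMM. Small losses of single genes may be missed by spike-ins, where a 1.5-fold change is recovered for 43.3%, 47% and 74.6% of genes in the spt3, spt8 and gcn5 comparisons. With TMM these shares are 97%, 90.9% and 92.5%. Each comes from a single simulation, so differences between strains by spike-ins may reflect the scaling errors drawn. A planted list raised 1.5-fold, with genes simulated as independent, was found by spike-ins in each (limma camera, BH-adjusted p of 4.05e-20, 2.82e-19 and 1.08e-19). A smaller common change was not simulated.

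Falls were more frequent among all genes that SM induced. They are lower levels than in WT with SM. As no deletion strain without SM is included, loss of induction cannot be told from lower levels before SM. Genes that SM raised at least 2-fold, 1940 in all and chosen on these same samples, include ARG3 and STR3 but also many outside amino acid synthesis. In the spt3 strain 436 of them fell (22.5%), 201 rose and 1303 did not pass, against falls in 483 of the 4624 other genes (10.4%; odds ratio 2.49, Fisher exact p = 4.09e-35). In gcn5 719 fell (37.1%), 182 rose and 1039 did not pass, against 1275 others (27.6%; odds ratio 1.55, Fisher exact p = 4.63e-14). In spt8 129 fell (6.6%), 98 rose and 1713 did not pass, against 237 others (5.1%; odds ratio 1.32, Fisher exact p = 0.0156), and the 129 become 75 without WT library 2 and 72 without spt8 library 1. With TMM the induced set has 1111 genes, and 545, 301 and 417 of them fell in spt3, spt8 and gcn5 (Fisher exact p of 1.65e-41, 1.43e-07 and 0.00132 against other genes). WT with SM serves both sides of this comparison. Simulated groups without any real difference gave 0.1, 0.15 and 0.45 falls on average, and 0.15, 0.1 and 0.8 among other genes, too few to say whether sharing favours falls among induced genes. Their covariances with the induction were −0.00831, −0.00951 and −0.00769, against −0.154, −0.0416 and −0.104 measured. In spt8 the correlation with the induction (−0.0864) lies within the simulated range (−0.108 to −0.0309), though that range comes from strains that do not differ. The covariance lies outside its own simulated range (−0.0159 to −0.00451). The median of its induced genes is 0.04 by spike-ins (0.04 simulated), against 0.16 for other genes (0.05 simulated). With TMM these medians are −0.13 (−0.01 simulated) and 0.03 (0.001 simulated). In a test chosen after the data were seen, separate WT libraries with SM served each side, 1 against 2 in all 6 ways. Covariances were then −0.135, −0.0316 and −0.0897 on average in spt3, spt8 and gcn5, against −0.143, −0.0393 and −0.0966 with the same libraries on both sides. Medians of induced minus other genes were −0.282, −0.107 and −0.155 on average, against −0.293, −0.116 and −0.167. Counts of calls were not repeated this way, as one side keeps 1 library, so part of their excess may come from sharing. Genes are not independent, which makes the Fisher p too small.

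The spt3 and spt8 strains changed many genes in common, among them HXK1, GPH1, GAC1 and HXT7 downward and DRS1, RRP12 and SER3 upward. Rises called in both number 407 (93.6 expected as product of the counts over all genes) and falls 352 (51.2 expected), with 0 opposite. The spt3 and gcn5 strains had 420 rises (150 expected) and 531 falls (279 expected) in common, and 179 genes in opposite directions. For spt8 and gcn5 these are 207 rises (45.4), 225 falls (111) and 72 opposite. Fold changes correlate at r = 0.875, 0.441 and 0.397. Sharing the WT libraries alone gives 0.5, 0.497 and 0.498 in simulation, with 0.05 genes called in both for spt3 and spt8. The simulated groups do not differ, so their fold changes hold noise alone. Those correlations therefore set no level for the measured ones, and covariances are compared instead. Covariances were 0.248, 0.186 and 0.111 against simulated 0.00849, 0.00851 and 0.00857. With separate WT libraries for each strain, 1 against 2 (chosen after the data were seen), covariances were 0.238, 0.177 and 0.104 on average over 6 splits, and correlations 0.825, 0.42 and 0.364. The counts in common were not repeated this way, as one side keeps 1 library, so part of their excess may come from the shared controls. With TMM the common genes are 1466 rises and 1242 falls (spt3 and spt8), 1312 and 1096 (spt3 and gcn5) and 1007 and 763 (spt8 and gcn5), against expected products of 532 and 434, 759 and 688, and 536 and 461. Genes in opposite directions are then 13, 649 and 441.

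**Figure D3:**
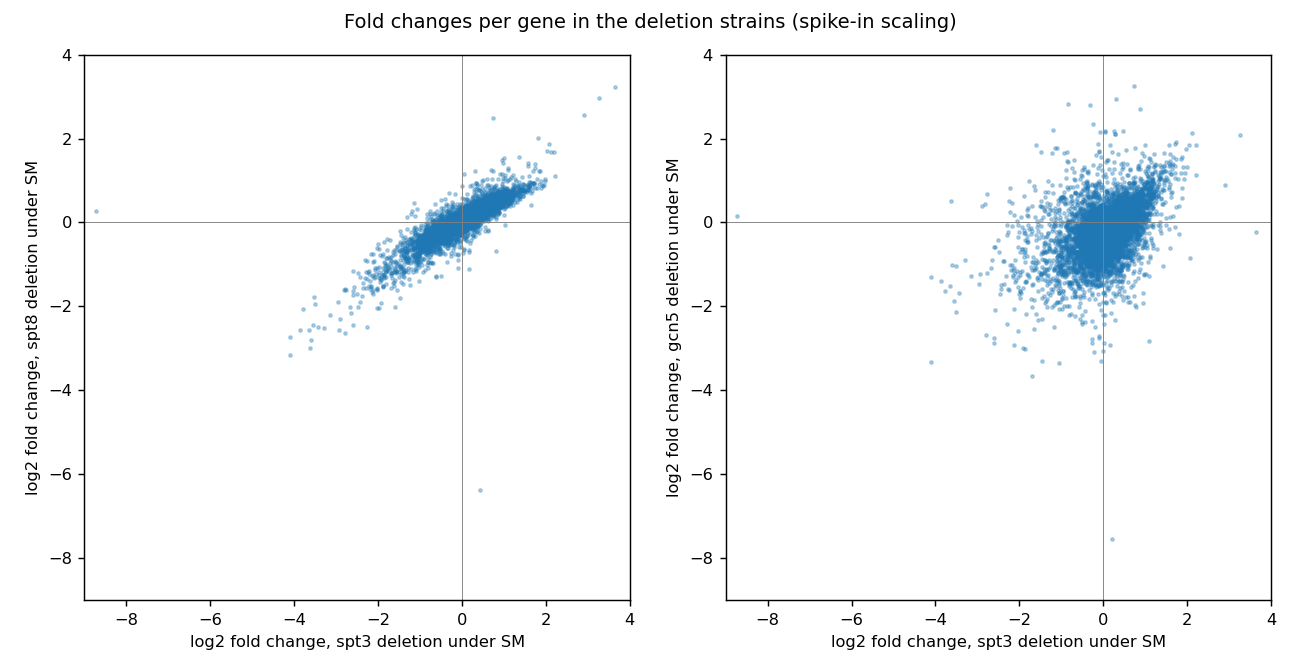
Log2 fold change against WT with SM for each gene, spt3 on the horizontal axis against spt8 (left, r = 0.875) and gcn5 (right, r = 0.441). All strains are compared with the same 3 WT libraries.

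Stress and ribosome biogenesis genes lay further from WT in spt3 than in spt8. Stress genes were lower in spt3, by a median of 0.61 log2, with 8 of 20 called, or 13 over the list alone and 13 with TMM (SOL4 −1.57, SE 0.23; HXK1 −1.31, SE 0.20; GPH1 −1.11), and GSY1, glycogen synthase, was lower by 1.44. Ribosome biogenesis genes were higher by a median of 0.45, with 5 of 46 called, or 21 over the list alone and 44 with TMM (ROK1 0.83, EBP2 0.79), and HO was higher by 1.11 (SE 0.21, edgeR BH-adjusted p = 0.0013). The ROK1 and EBP2 calls end without spt3 library 1, spt8 library 1 or spt8 library 3. By limma camera the BH-adjusted p were 3.86e-15 for stress and 6.05e-19 for ribosome biogenesis genes, both 0.992 with an estimated correlation. Of the 89 amino acid genes 0 differed in edgeR (median 0.04); with TMM 15 were higher and 10 lower. Over all genes 72 were higher, 157 lower and 6335 did not pass. The 72 become 8 without spt3 library 1, 24 without spt8 library 1, 31 without spt8 library 2 and 8 without spt8 library 3. The 157 become 54 without spt3 library 2, 78 without spt3 library 3, 61 without spt8 library 2 and 41 without spt8 library 3. With TMM 1107 are higher and 936 lower, so the share that is higher goes from 31.4% to 54.2%. The groups did not overlap in 1362 genes (20.7%, 10% by chance; 53.1% with TMM), and these strains lie in different library sets.

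Against gcn5, the spt3 strain had more mating mRNA and less hexose transporter mRNA. Of 12 haploid mating genes 10 were higher (median 1.38; FAR1 2.60, FUS1 2.02) and of 7 a-specific genes 6 (median 1.11; ASG7 2.29, and AFB1 outside the list at 3.06). Of 7 hexose transporter genes 6 were lower (median −1.53; HXT3 −2.48), and 14 of 20 stress genes were lower with 2 higher (median −0.72; HSP26 −2.39). Among arginine genes 2 were higher and 4 lower, led by ARG3 at −1.59 and ARG56 at −1.57. BH-adjusted p by limma camera were 1.68e-05 (haploid), 0.00116 (a-specific), 3.33e-11 (hexose transport), 1.35e-10 (stress) and 0.0241 (arginine). With an estimated correlation those adjusted p are 0.932, 0.932, 0.342, 0.932 and 0.988. Over each list alone the counts are the same but for hexose transport, with 7 lower. In all 2449 genes were higher, 638 lower and 3477 did not pass, with a median gene at 0.31 log2. That shift rests on the gcn5 libraries, where the spike-in species differed most. Without gcn5 library 3 the 2449 become 4204. With TMM 2208 are higher and 2009 lower, and the share that is higher goes from 79.3% to 52.4%. The groups did not overlap in 2514 genes (38.3%, 10% by chance; 63.9% with TMM), again across library sets.

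The spt8 and gcn5 strains, which lie in one library set, differed in many of these genes too. FAR1 was higher by 2.45 in spt8 and ASG7 by 2.63, with 10 of 12 haploid (median 1.14) and 6 of 7 a-specific genes higher (median 0.86). Ribosomal protein genes were higher in 85 of 132 cases and lower in 0 (median 0.47; RPL43A 2.19), or in 90 and 0 over the list alone and 56 and 13 with TMM. HXT2 was lower by 2.06, as were 5 of 7 hexose transporter genes (median −1.28), and ARG56 by 1.19 and ARG3 by 1.11. Stress genes split, with 5 higher and 8 lower (HSP26 −2.29); their median is 0.14 while limma camera points down (BH-adjusted p = 0.00416), a call that holds neither with TMM (0.228) nor with an estimated correlation (0.971). For the haploid, a-specific, ribosomal protein and hexose lists limma camera gave BH-adjusted p of 0.000668, 0.000668, 0.00275 and 5.15e-09. With an estimated correlation those adjusted p are 0.971, 0.971, 0.971 and 0.603. Over all genes 2435 were higher, 509 lower and 3620 did not pass, and the median gene lies at 0.30 log2. This shift too rests on the gcn5 spike-ins. The 2435 become 1586 without gcn5 library 2 and 4168 without gcn5 library 3. With TMM 2039 are higher and 2052 lower, and the share that is higher goes from 82.7% to 49.8%. The groups did not overlap in 2866 genes (43.7%, 10% by chance; 63.3% with TMM).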

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

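For the 3 patterns weighed here, the tests of gene length and GC content and of uniform background reads were written before their results were seen; the tests of spike-in scaling, intact GCN5 cells, WT libraries out of line, library set and splits were chosen only after the results were seen. A first form of the test on WT libraries was replaced after its result was known, and the replacement turned both of its readings round. The gaps between further pairs of strains were also computed after the results were seen.

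SM in WT raised most yeast genes against the spike-ins. Uniform background reads would add little per kilobase, but 99.9% of the genes that rose at least 2-fold, ARG3 among them, gained more than the 8.9 reads per kilobase of the 1st percentile under SM (median gain 846.6), so this is not the cause. An error in spike-in scaling could lift all genes alike, yet 74.1% of the risen genes also rise with TMM, which argues against it for those genes. For the common shift, a median gene rise of 0.54 log2, it stays open. That median was not tested itself, only the ratio of all yeast counts to spike-ins (37.6 ± 3.62 against 31.9 ± 0.93). An exact permutation of this ratio gives p = 0.1, the smallest possible with 3 against 3 (n = 3).

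Library 3 of gcn5 differs from libraries 1 and 2, with a spread of gene deviations of 0.26 log2. Trends with gene length and GC content carry 28.0% of that variance, and without them the spread is 0.22, which is 1.51 times the highest of the 12 libraries outside this group (0.14), so they may be a part but are not the whole. Cells with an intact GCN5 gene are no likely cause, as GCN5 stands at 0.52% of its WT level. A biological cause was not tested.

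Ribosome biogenesis genes rose and Msn2 and Msn4 stress genes fell in all 3 strains. Trends with length and GC content do not account for it: after their removal the smallest biogenesis median is 0.34 (spt8) and the stress median nearest 0 is −0.81 (gcn5). WT libraries with SM that were out of line could not by themselves set strains apart. Between spt8 and gcn5, in the same library set, the nearest libraries are 2.65 SDs apart for biogenesis genes and overlap for stress genes (−0.24). Across sets the gaps are 3.56 (spt3, spt8) and −0.62 (spt3, gcn5, an overlap) for biogenesis and 0.94 and 2.48 for stress. An overlap decides nothing, as strains with like changes would overlap too, so stress genes stay open in this test. Relative to all genes, the stress median was −0.818 or lower in every deletion library. It was −0.067 to 0.031 in WT with SM and 0.648 to 0.792 in WT without SM, which lacks the SM effect. The gaps argue only against WT as the whole cause in every strain, and a part may come from it. The first form, against WT without SM, had put biogenesis in spt8 at 0.025 and every stress median at −1.531 or below. It left biogenesis open and stress not. Library set is not the cause in spt3, where 95.7% of biogenesis genes, such as DRS1, rose within the set of WT, but for spt8 and gcn5 the second set holds 0 WT libraries and set and deletion cannot be told apart.

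The 10 ways to split 6 libraries cannot give a share under 0.05; in fits of 2 groups the real split gave the most calls in every comparison (1 of 10 splits). Real and highest other numbers of called genes were 5033 and 0 for SM in WT, 2534 and 0 for spt3, 2508 and 0 for spt8, 1927 and 0 for gcn5, 662 and 15 for spt3 against spt8, 1890 and 0 for spt3 against gcn5, and 2208 and 0 for spt8 against gcn5.

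Other results stood out. Between spt3 and spt8, 8 lists differed under both scalings by limma camera: ribosomal proteins by −0.12, ribosome biogenesis by 0.45, chaperones by 0.23, Msn2 and Msn4 stress by −0.61, hexose transporters by −0.29, citrate cycle by −0.29, haploid mating by 0.20 and TFIID and TBP regulators by 0.22 (median log2). The ribosomal protein call ends with the replicate number as a block. Removing trends with gene length and GC content takes that list from −0.134 to −0.054 relative to genes with a mean count of 300 or more. Between spt3 and gcn5 these were arginine at −0.033, stress at −0.72, hexose transporters at −1.53, a-specific at 1.11, haploid mating at 1.38 and the mitochondrial genome at −0.63. Between spt8 and gcn5 they were arginine at −0.10, ribosomal proteins at 0.47, ribosome biogenesis at −0.16, glycolysis at −0.058, hexose transporters at −1.28, a-specific at 0.86, haploid mating at 1.14 and the mitochondrial genome at −0.63. These medians hold the common shift, as the median gene lies at 0.31 (spt3, gcn5) and 0.30 (spt8, gcn5). Relative to genes with a mean count of 300 or more, arginine is at −0.359 and −0.398. Between spt8 and gcn5, ribosomal proteins are then at 0.166, ribosome biogenesis at −0.466 and glycolysis at −0.36. Without the same trends the relative mitochondrial median goes from −0.956 to −0.428 (spt3, gcn5) and from −0.93 to −0.488 (spt8, gcn5). None holds with an estimated correlation, where the adjusted p of limma camera (BH) are 0.992 for the first comparison, 0.342 to 0.988 for the second and 0.603 to 0.971 for the third. LEU2, MET15 and URA3, absent from the parent strain, had 70, 82 and 7 counts in library 1 of WT without SM and at most 6, 4 and 2 in the other libraries. That library may hold a trace of another strain, and it is 1 of the 3 that every SM result is measured from. Without it 3345 genes rise and 394 fall with SM, against 3653 and 497, and of 128 results on named genes 0 change in call or sign.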

How the results depend on the processing

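Counts of genes that rose or fell were recomputed under settings fixed beforehand, and 7 were added after seeing the data (spt3 library 1 and gcn5 library 3 left out together, by spike-ins and with TMM; each of them left out with TMM; for the lists only, an estimated correlation with TMM; and, for covariances only, separate WT libraries with SM, and for groups that do not overlap only, TMM). Overlaps between strains were recomputed with TMM and the replicate block, and SM-induced counts under fewer settings. The cause of a shift between settings was not tested. Of 686 results on named genes, 670 were called, 523 kept the call everywhere, 147 lost it somewhere and 15 changed sign somewhere. With DESeq2 on the same spike-in factors 2 lost the call. With a stricter filter (mean count of 50 or more) 0 of the 682 results it kept did, and with no filter 0 of 686. Fits of only the 2 groups lost 65 and the replicate block 42.

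With TMM, genes that fell with SM were 2445. In spt3 2223 rose and 2061 fell, in spt8 1570 rose and 1382 fell, and in gcn5 2241 rose. Between strains, 1107 were higher and 936 lower in spt3 than in spt8, 2009 lower in spt3 than in gcn5, and 2052 lower in spt8 than in gcn5. Of the SM-induced genes 301 fell in spt8 and 417 in gcn5. Rises and falls in common were 1466 and 1242 (spt3 and spt8), 1312 and 1096 (spt3 and gcn5) and 1007 and 763 (spt8 and gcn5). Lists called upward were 2 in spt3 and 2 in spt8. SPT3 and SPT8 turned to −0.20 and −0.28 for SM in WT, and SPT3 to −0.17 between spt8 and gcn5.

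DESeq2 with its default size factors gave 2785 falls for SM, 2263 falls for spt3, 1708 rises and 1395 falls for spt8, 2253 rises for gcn5, 1013 higher and 1239 lower between spt3 and spt8, 2187 lower between spt3 and gcn5, and 2058 lower between spt8 and gcn5. For SM in WT it turned ERG27 to −0.006, IDH1 to −0.055, MOT1 to −0.032, SPT3 to −0.28 and SPT8 to −0.36. GCN5 turned to −0.003 between spt3 and spt8, and SPT3 to −0.16 between spt8 and gcn5. Scaling by total spike-in counts gave 800 falls for SM and 757 rises for spt8, and GCN4 between spt3 and spt8 became 0.0.

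Fits of only the 2 groups gave 812 falls for SM, 1742 rises and 766 falls for spt8, 451 rises for gcn5, 284 higher and 378 lower between spt3 and spt8, and 1460 higher between spt3 and gcn5.

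With the replicate block, lists called upward in gcn5 were 1 in place of 2; the citrate cycle and mitochondrial calls in gcn5 ended (limma camera, BH-adjusted p of 0.0571 and 0.0545), as did ribosomal proteins between spt3 and spt8 (0.0585). No count of called genes moved by 1.5 times. The replicate block with TMM gave 2402 falls for SM, 2168 rises and 2012 falls for spt3, 1472 and 1326 for spt8, and 2170 rises for gcn5. Between strains it gave 978 higher and 848 lower (spt3, spt8), 1964 lower (spt3, gcn5) and 1984 lower (spt8, gcn5); SPT3 was −0.20 and SPT8 −0.27 for SM, and SPT3 −0.17 between spt8 and gcn5. Replicate numbers do not pair the samples: of 30 pairs with the same number 7 correlated above 0.1 (range −0.38 to 0.24), and 3 libraries were closest to one of their own number.

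Without spt3 library 1 and gcn5 library 3, by spike-ins, SM gave 860 falls, spt3 1748 falls, spt8 2100 rises and 801 falls, and gcn5 3817 falls. Between strains 204 were higher and 1254 lower (spt3, spt8), 3711 higher (spt3, gcn5) and 4553 higher (spt8, gcn5). GCN4 became 0.069 between spt8 and gcn5, GCN5 −0.12 between spt3 and spt8, and SPT3 −0.14 in gcn5. With TMM the same libraries left out gave 2587 falls for SM, 2250 rises and 2056 falls for spt3, 1848 and 1608 for spt8, 2196 rises for gcn5, 1124 higher and 962 lower (spt3, spt8), 1964 lower (spt3, gcn5) and 2065 lower (spt8, gcn5). GPM1 became −0.025 and SPT3 −0.075 between spt8 and gcn5, PDC1 −0.007 and THR1 −0.13 between spt3 and gcn5, THR1 0.048 in gcn5, and SPT3 −0.20 and SPT8 −0.28 for SM.

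TMM without gcn5 library 3 alone gave 2164 rises for gcn5, 2029 lower (spt3, gcn5) and 2041 lower (spt8, gcn5). There GPM1 was −0.025 and SPT3 −0.075 between spt8 and gcn5, PDC1 −0.044 and THR1 −0.14 between spt3 and gcn5, and THR1 0.048 in gcn5. TMM without spt3 library 1 alone gave 1833 falls for spt3, 726 higher and 684 lower (spt3, spt8) and 1913 lower (spt3, gcn5).

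Between the scalings 15 list calls differ. By limma camera (BH) with TMM, these pass and do not by spike-ins: aromatic (0.00385) and iron (0.0308) for SM; ribosomal proteins (0.00701) and TFIID and TBP regulators (0.0345) in spt3; tRNA synthetases in spt8 (0.0466); arginine in gcn5 (0.0439); lysine (0.0183) and inositol (0.0388) between spt3 and spt8. The reporter panel, respiratory and SAGA lists pass with it between spt3 and gcn5 (limma camera, BH-adjusted p of 0.0214, 0.00352 and 0.0214), and the reporter panel and respiratory lists between spt8 and gcn5 (0.0136 and 0.0136). None of these 13 passes with an estimated correlation and TMM (0.256 or above). The mitochondrial list in gcn5 (0.0949) and stress between spt8 and gcn5 (0.228) no longer pass. For the lists, an estimated correlation left 0 called in either direction in all 7 comparisons by spike-ins. With TMM it left 6 upward and 2 downward for SM, 1 downward and 0 upward for gcn5, and 0 both ways elsewhere. The fry test of limma gave 19 upward and 4 downward for SM, 0 and 2 for spt8, 1 upward for gcn5, 0 and 0 for spt3 against spt8, 13 upward for spt3 against gcn5, and 12 and 2 for spt8 against gcn5. With no minimum fold change 1192 SM-induced genes fell in gcn5.

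Leaving out 1 library at a time, the lowest and highest counts were 3153 to 3757 rises and 321 to 502 falls for SM, 781 to 1581 and 697 to 1049 for spt3, 118 to 309 and 226 to 335 for spt8, and 426 to 883 and 1452 to 3364 for gcn5. Between strains they were 8 to 73 higher and 41 to 175 lower (spt3, spt8), 1639 to 4204 and 494 to 717 (spt3, gcn5), and 1586 to 4168 and 364 to 585 (spt8, gcn5). SM-induced genes that fell were 309 to 484 in spt3, 72 to 133 in spt8 and 517 to 1029 in gcn5. Among the regulators, which were not called here, SPT3 ran from −0.15 to 0.31 in gcn5 and −0.03 to 0.42 between spt8 and gcn5, GCN5 from −0.12 to 0.10 between spt3 and spt8, and GCN4 from −0.17 to 0.085, −0.24 to 0.062 and −0.19 to 0.066 between spt3 and spt8, spt3 and gcn5, and spt8 and gcn5.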

Other observations

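Many nutrient genes outside amino acid synthesis rose with SM in WT by spike-ins, as did 3653 of all 6564 genes tested. In the phosphate list 8 of 13 rose and 0 fell (8 and 1 over the list alone), the transporter genes PHO89 by 2.70 log2 and PHO84 by 2.34; with TMM 8 rose and 5 fell. In the iron list 9 of 13 rose and 0 fell (9 over the list alone; FRE2 by 2.39), and with TMM 8 rose and 4 fell. Amino acid permease genes rose in 11 of 15 cases (11 over the list alone; ALP1 by 2.49), and with TMM 8 rose and 3 fell. By spike-ins none of these lists passed with limma camera against other genes (BH-adjusted p of 0.265 for phosphate, 0.171 for iron and 0.331 for permeases). With TMM the iron list passes upward (limma camera, BH-adjusted p = 0.0308, or 0.3 with an estimated correlation). Cytosolic tRNA synthetase genes gave 1 rise and 4 falls in 18 (also over the list alone; SES1 −0.99; 0 and 17 with TMM), 0.55 below the median gene (limma camera, BH-adjusted p = 0.000991; 0.837 with an estimated correlation). In spt3 7 of 13 iron genes rose and 1 fell (also over the list alone, and 8 and 3 with TMM; TIS11 1.42), and in spt8 3 rose and 1 fell (7 and 1 over the list alone; TIS11 1.07). In gcn5 the list gave 2 rises and 5 falls, and with TMM 6 and 5. The iron list passed in none of the 3 strains by limma camera (BH-adjusted p of 0.207, 0.213 and 0.82).

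Hypothesis: since Spt3 and Spt8 were first found through their effect on Ty elements, Ty mRNA would fall when either is lost. The fixed list matched 0 features, so 89 Ty gag and gag-pol features were taken by name. The test, written before its result, asked whether over 50% of them fall in both strains: 26 fell and 7 rose in spt3 (median −0.07), and 24 fell and 1 rose in spt8 (−0.40). The smaller share is 27.0%, so the broad hypothesis, as set, is not borne out. Falls were still more frequent than over all 6564 genes tested, of which 919 fell in spt3 and 366 in spt8. The Ty median lies 0.18 and 0.52 below that of all genes in these strains. By family, a division chosen after the result was seen, Ty1 gave 23 falls and 4 rises in 60 for spt3, 20 and 0 for spt8 and 32 and 1 for gcn5, while Ty2 gave 3 falls in 20 for spt3 (1 rise), 3 for spt8 and 0 for gcn5. With TMM the families do not part in spt8, where 44 of 60 Ty1 and 14 of 20 Ty2 features fell, and in gcn5 9 Ty2 features rose. Of the 89, 35, 59 and 35 fell with TMM in spt3, spt8 and gcn5, and 18, 1 and 22 rose. Copies are near-identical, so reads may be shared between them or lost. Counting unique and shared reads apart, or a probe for Ty1 RNA, would test this.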
